A study of Homo sapiens with 52 samples.

How the data were processed

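RNA was sequenced from HepG2 and Huh6 cells (31 libraries) and from THP-1 macrophages (21 libraries), 52 libraries in all. HepG2 and Huh6 are hepatoblastoma lines and THP-1 is a monocytic leukaemia line, here turned into macrophages with PMA. RNA was extracted with RNeasy and libraries were made with poly(A) selection and a directional kit, per the labels' protocols. The submitters' processing notes name STAR 2.7.3a, SAMtools 1.16.1, featureCounts and edgeR 3.36 on GRCh38. The featureCounts version, the annotation release and the strand setting are not given in the sources used here. The values are raw read counts per gene, as deposited in a table for the tumour lines (62696 genes with identifiers and symbols) and a table for THP-1 (61209 genes by symbol only). Every THP-1 symbol occurred in the tumour line table, and 0 per-sample columns were left unused. Coordinates of the genes given with a position come from a GENCODE 29 gene table on GRCh38 and were matched by gene identifier.

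Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Genes passed the filterByExpr filter by group, libraries were scaled by TMM, and groups were compared with the two-sided quasi-likelihood F test in a model of group means. P values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, with a threshold of 0.05. Each line was fitted on its own, with one estimate of the spread for all of its groups. Tests of a difference between lines (interactions) used the 4 groups concerned. CPM are TMM-scaled counts relative to library size, computed from the deposited counts. Shares of reads, their limits on CPM and the HepG2 values of GPNMB, CFD and CD74 use CPM without TMM. Values are means ± SD of 3 libraries and log2 fold changes ± SE, from 3 libraries per group. This SE is the size of the change divided by the square root of its F statistic, not an estimate made by the fit. For large changes from a control near 0 it can understate the error. Where a control group had a count of 0, the fold change is a lower bound that allows 3 counts in that group. Bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

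The 21 comparisons, their tests, 31 gene lists and the rule for naming genes were fixed before the data were examined. The rule allowed, in each main comparison, the 8 genes with the highest and the 8 with the lowest log2 fold change, provided that the gene passed the threshold, had a mean log2 CPM of at least 2, had a symbol that is not a clone name, and had 3 values of one group that did not overlap the 3 of the other, which happens by chance for 10% of genes. In THP-1 a gene also had to pass, in the same direction, after subtraction of the estimated tumour reads. The rule further allowed up to 4 passing members of each gene list with the largest change, 5 genes per direction in tests of a difference, and a fixed set of genes that is always given. MDK, CTNNB1, AXIN2, LGR5, NKD1, NOTUM, SP5, LEF1, AFP, GPC3 and ALB were always given in tumour cells, and CD163, MRC1, IL1B, TNF, CD274, CD86, HLA-DRA and LRP1 in THP-1. SP5 and MRC1 had too few counts to be tested. The liver genes AHSG and RBP4 had 0 counts in both tables, and whether the annotation or the counting left them out is not known. For other doses the rule allowed genes named in the main comparison of the same inhibitor and line. The genes in the text are a selection from those the rule allows, made after their values were seen, and genes outside the rule are identified as such.

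Gene lists were tested with camera, two-sided, with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The alternative estimated that correlation from the residuals. Counts of list members are given over all genes tested, and adjusted over the list alone where that count differs. The lists for both kinds of cell were MDK with its reported receptors, the cell cycle, p53 targets, NRF2 targets, the ATF4 integrated stress response, endoplasmic reticulum chaperones, heat shock, cholesterol synthesis, aryl hydrocarbon receptor targets, hypoxia, metallothioneins, MHC class I, interferon-stimulated genes, chemokines and cytokines, checkpoint genes, mitochondrially encoded genes, ribosomal proteins and macrophage identity. Lists for the tumour lines alone were Wnt/beta-catenin targets, pericentral, hepatocyte, fetal liver and mesenchymal genes. Lists for THP-1 alone were inflammatory, alternative activation, lipid-associated, MHC class II, NF-kappaB feedback, phagocytosis, matrix and hepatoblastoma marker genes.

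The share of tumour reads in a THP-1 library was the median, over hepatoblastoma markers of at least 100 CPM in the tumour line, of the excess over monoculture divided by the CPM of the matching tumour line group. Groups match by line and dose only. The tumour line groups were treated for 48 h, whereas co-cultured tumour cells had received iMDK for 24 h before 24 h of co-culture. Groups were compared by an exact two-sided permutation test, whose smallest possible p is 0.1 with 3 against 3. For the subtraction alternative, each library's share times the matching tumour profile was taken off its counts. The only library of HepG2 at 0.3 uM PKF118-310 was not tested. Its values are differences of log2 CPM (prior count 2) from the vehicle mean, and list medians were ranked among 10000 random lists matched for expression in 20 bins.

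Replicate numbers occur in every group, and the labels do not say what they stand for. In THP-1, libraries with the same number deviated together from their group means (mean correlation across genes 0.442). The mean for other numbers (-0.217) is pushed below 0 by the centring on group means. For 21 of 21 libraries the mean correlation was highest with the libraries of their own number. The pairing therefore comes from the data, not the labels. Every pair's correlation was over 0.1 in the paired comparisons, which are all except those with iMDK 10 uM pretreated Huh6, where the lowest was 0.0823. Values from the fit with the replicate number as a block are given beside those results where they differ in their call.

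Alternatives fixed in advance were the RLE scaling of DESeq2, the DESeq2 1.42.0 Wald test, no filter on low counts, a replicate block, only the groups compared, each library left out in turn, all libraries (tests of a difference), an estimated correlation (lists), subtracted tumour reads (THP-1), other markers for the share (at least 20 CPM, or all tumour-specific genes), and a prior count of 0.5 (single library). After the data were seen, 4 more were added for THP-1: subtraction at a lower share, only genes no higher in the tumour line, leaving out all libraries numbered 1, and the block with only genes no higher in the tumour line. Apart from the settings named as a block, the alternatives were run without it. In THP-1, calls lost with those settings were therefore lost with the pairing ignored. On simulated counts for Huh6 with 0.2 uM PKF118-310 (15029 genes, 100 changed at each size), edgeR recovered 91% of genes changed by a log2 of 1 and 99% of those changed by 2, with 10 false calls. For HepG2 with 0.2 uM PKF118-310 (15451 genes) it recovered 92% and 98% with 12 false calls, and for THP-1 with untreated HepG2 (15500 genes) 84% and 97% with 6.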

Results

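The libraries measured poly(A) RNA of hepatoblastoma cells under inhibitors of Wnt and MDK signalling, and of macrophages that had shared a culture with those cells, to ask how both pathways shape the tumour cells and their immune surroundings. PKF118-310 disrupts the complex of beta-catenin with its TCF partners, and iMDK lowers the growth factor midkine (MDK). HepG2 and Huh6 cells were treated for 48 h with PKF118-310 (0.2, 0.3 or 0.4 uM), iMDK (5 or 10 uM) or vehicle. THP-1 macrophages were cultured alone, or for 24 h with tumour cells that were untreated or had received iMDK for 24 h, and were then sorted. Each group had 3 libraries, except HepG2 at 0.3 uM PKF118-310 with 1, and the 0.4 uM dose was used in Huh6 only. Whether the 3 libraries of a group come from separate cultures is not stated in the labels, so n counts libraries. Total counts per library were 18.3 to 20 M in HepG2, 18.2 to 19.9 M in Huh6 and 12.6 to 16.9 M in THP-1, at which 3 counts correspond to 0.15 to 0.164, 0.151 to 0.165 and 0.177 to 0.238 CPM. The edgeR tests covered 15451, 15029 and 15500 genes, respectively.

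In Huh6, which was treated with PKF118-310 to ask what inhibition of beta-catenin changes, 0.4 uM raised stress and detoxification genes and lowered liver genes. The zinc-binding metallothionein MT2A rose by a log2 fold change of 3.93 ± 0.049 (297 ± 10 against 19.5 ± 1.56 CPM, n = 3, adjusted p = 3.04e-43), and MT1G, whose close paralogues share sequence with it, rose by 3.3 ± 0.086. The NRF2 targets OSGIN1 (3.43 ± 0.066) and TXNRD1 (1.71 ± 0.025), the stress-induced transcription factor ATF3 (3.05 ± 0.045), the cytokine GDF15 (2.69 ± 0.033) and the natriuretic peptide gene NPPB (4.83 ± 0.1) rose as well. Fetal and adult liver products fell. The alpha-fetoprotein gene AFP changed by -2.09 ± 0.068 (15.1 ± 0.81 against 64.3 ± 5.16 CPM, adjusted p = 8.74e-28), the fatty acid binding protein FABP1 by -3.32 ± 0.12 and the apolipoprotein APOC3 by -2.51 ± 0.049. The fibrinogen chain FGA changed by -2.26 ± 0.055, the urea cycle gene CPS1 by -1.89 ± 0.046 and the growth factor IGF2 by -1.36 ± 0.032. The change was smaller for the oncofetal gene GPC3 (-0.66 ± 0.02), and ALB, which was low in this line (2.85 CPM), changed by -1.58 ± 0.25. In all, 4342 genes were higher and 4190 lower, of which 557 and 843 changed at least 2-fold.

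By gene list, all 19 measured hepatocyte genes fell at 0.4 uM (median -1.06, adjusted p = 3.15e-49), as did 7 of 8 pericentral genes (5.52e-06) and 9 of 14 fetal liver genes (2 rose, 6.61e-07). All 16 NRF2 targets rose (8.49e-33), as did all 4 metallothioneins (median 3.62, 1.07e-26), and 14 of 16 integrated stress response genes (1 fell, 7.87e-26). Higher too were 14 of 19 p53 targets (2 fell, 1.03e-23), 10 of 11 heat shock genes (5.45e-06) and 10 of 15 hypoxia genes (3 fell, 0.00144), while 18 of 21 cholesterol synthesis genes fell (4.12e-17). Of 27 cell cycle genes, 17 fell and 4 rose (median -0.19, 0.000298). Further calls that ended with an estimated correlation were those of the 14 mesenchymal genes (8 rose and 4 fell, or 5 adjusted over the list alone, adjusted p = 6.44e-05, 0.0571 with an estimated correlation), of the ribosomal proteins (24 of 25 rose, 0.00782, then 0.345) and of the endoplasmic reticulum chaperones (11 of 15 fell and 3 rose, 0.0289, then 0.183).

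The Wnt/beta-catenin targets did not move together in Huh6. At 0.4 uM, 12 of 16 measured targets fell and 4 rose (adjusted p = 0.0289, 0.127 with an estimated correlation). The secreted antagonist DKK1 changed by -0.97 ± 0.025 (308 ± 5.31 against 601 ± 8.33 CPM), the feedback inhibitors NOTUM by -0.5 ± 0.082 and NKD1 by -0.35 ± 0.027. The stem cell receptor LGR5 changed by -0.34 ± 0.064 and the TCF family member LEF1 by -0.34 ± 0.062, while MYC rose by 1.14 ± 0.043. AXIN2, the scaffold of the complex that degrades beta-catenin and a common readout of the pathway, rose by 0.11 ± 0.028 (218 ± 4.03 against 202 ± 3.23 CPM, adjusted p = 0.000817), and CTNNB1, which encodes beta-catenin, by 0.07 ± 0.021 (0.00496). AXIN2 (ENSG00000168646.12) lies on chromosome 17 at 65528563 to 65561647 of GRCh38, and NOTUM (ENSG00000185269.11) on the same chromosome at 81952507 to 81961840. MDK (ENSG00000110492.15, chromosome 11, 46380756 to 46383837) fell by 0.39 ± 0.025 on the log2 scale (327 ± 9.04 against 429 ± 11.3 CPM, 2.48e-17).

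Lower doses gave part of this response in Huh6. MT2A rose by 0.46 ± 0.064 at 0.2 uM and 2.35 ± 0.053 at 0.3 uM, and GDF15 by 0.42 ± 0.036 and 1.63 ± 0.034. APOC3 changed by -0.48 ± 0.04 and -1.24 ± 0.043, and AXIN2 did not change detectably (-0.04 ± 0.028, adjusted p = 0.635, and 0.05 ± 0.028, 0.177). At 0.2 uM, 157 genes were higher and 180 lower, and at 0.3 uM 2254 and 2023. Already at 0.2 uM, 12 of 19 p53 targets rose (17 adjusted over the list alone, adjusted p = 2.61e-36) and 9 NRF2 targets (13 over the list alone, 3.55e-22), and 9 hepatocyte genes fell (10 over the list alone, 2.3e-21). The 4 hypoxia genes that changed at 0.2 uM were lower (9 over the list alone, 9.74e-10), the opposite of 0.4 uM. Directly between 0.4 and 0.2 uM, 4225 genes were higher and 3981 lower, including all 19 hepatocyte genes lower (1.14e-44), 14 of 16 NRF2 targets higher with 1 lower (1.1e-27) and all 4 metallothioneins higher (4.55e-27).

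**Figure D1:**
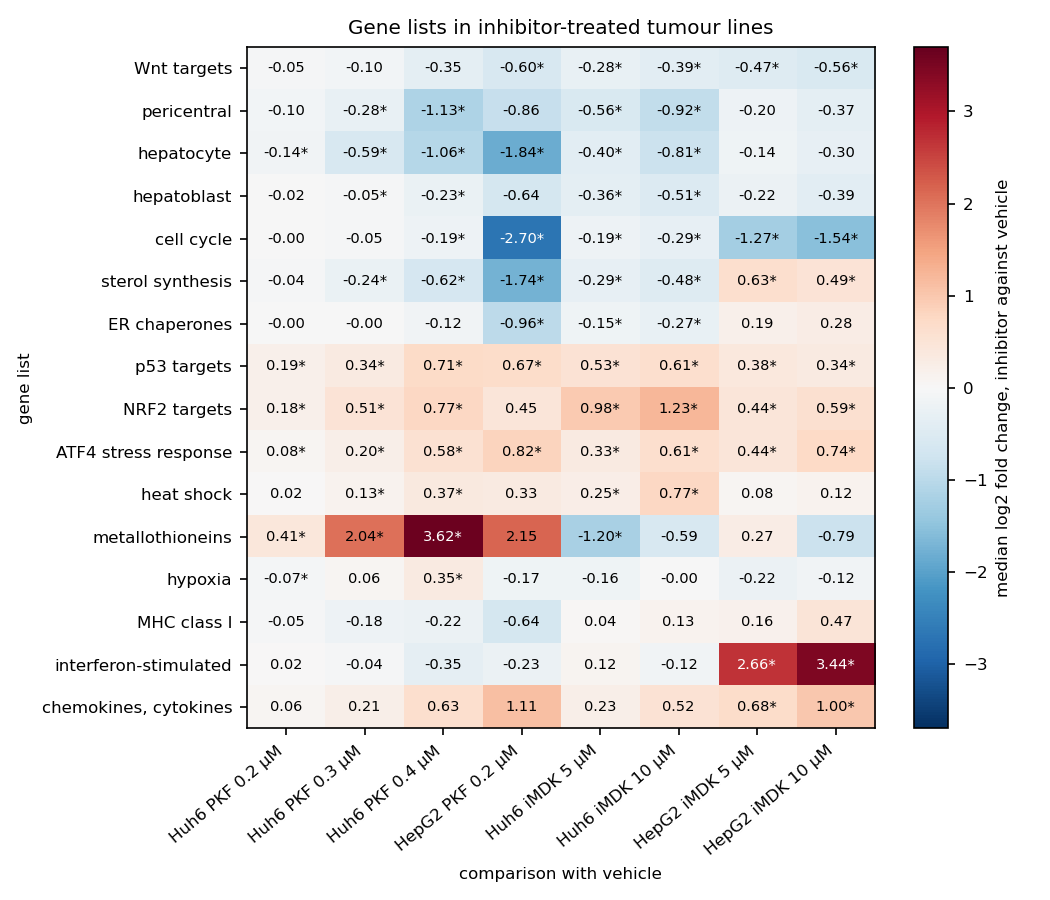
Median log2 fold change of 16 gene lists (vertical) in 8 comparisons of treated with vehicle cells (horizontal), with PKF standing for PKF118-310, and stars where the list passed the test with both the preset and an estimated correlation. Interferon-stimulated genes stand out in HepG2 with iMDK (median 3.44 at 10 uM), and the cell cycle list is lowest in HepG2 with PKF118-310 (median -2.7).

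HepG2 responded to 0.2 uM PKF118-310 with 5293 genes higher and 5162 lower, of which 1812 and 1893 changed at least 2-fold. Proliferation genes fell. The DNA topoisomerase TOP2A changed by -3.32 ± 0.038 (72.2 ± 4.02 against 719 ± 21.6 CPM, n = 3, adjusted p = 8.25e-42), MKI67 by -3.46 ± 0.059 and CCNA2 by -3.13 ± 0.061, with all 27 cell cycle genes lower (median -2.7, 6.49e-70). The plasma protein genes of the hepatocyte fell with them, ALB by 3.18 ± 0.039 on the log2 scale (693 ± 42.3 against 6290 ± 287 CPM), TF by 3.02 ± 0.042 and APOA1 by 2.55 ± 0.041. So did AFP (-2.88 ± 0.038), PEG10 (-2.27 ± 0.04), GPC3 (-1.54 ± 0.03) and the bile acid receptor NR1H4 (-3.52 ± 0.099). The cholesterol synthesis gene ACAT2 changed by -2.98 ± 0.053. The matrix protease MMP3 rose from 0.337 ± 0.177 to 600 ± 57.3 CPM (10.75 ± 0.1, 5.86e-44), followed by IGFN1 (8.07 ± 0.13), NAV3 (6.85 ± 0.13), the ligand WNT7B (6.59 ± 0.11) and the neurotensin receptor NTSR1 (6.12 ± 0.097).

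By gene list, 20 of 22 hepatocyte genes fell with 1 higher (median -1.84, adjusted p = 1.15e-25), as did 19 of 20 cholesterol synthesis genes (1 rose, 8.97e-27) and 13 of 15 endoplasmic reticulum chaperones (2 rose, 8.24e-09), including PDIA4 (-1.88 ± 0.03). The cell cycle inhibitor CDKN1A rose by 2.49 ± 0.032 (1030 ± 15.6 against 183 ± 3.31 CPM) among 11 of 19 p53 targets that rose (5 fell, 2.08e-06), and PPP1R15A by 3.58 ± 0.037 among 12 of 15 integrated stress response genes (2 fell, 6.66e-13). Further lists passed only with the preset correlation: NRF2 targets (10 of 15 rose, 3 fell, 5.19e-05, 0.0688 with an estimated correlation), with the cystine carrier SLC7A11 at 3.37 ± 0.073, and metallothioneins (4 of 5 rose, 1 fell, 5.19e-05, then 0.0688), with MT2A at 3.25 ± 0.035. So did aryl hydrocarbon receptor targets (3 of 4 rose, 1 fell, 0.0437, then 0.114), with CYP1A1 at 2.74 ± 0.068. Others were fetal liver genes (10 of 14 fell, 4 rose, 0.000233, then 0.129), pericentral genes (6 of 10 fell, 3 rose, 0.015, then 0.0688), MHC class I genes (10 of 13 fell, 1 rose, 0.0252, then 0.403) and mitochondrially encoded genes (12 of 13 fell, 1 rose, 0.0012, then 0.457). Mesenchymal genes were not called (5 of 13 rose and 5 fell, 0.596).

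Among 15 Wnt/beta-catenin targets in HepG2, 9 fell (10 adjusted over the list alone) and 3 rose at 0.2 uM (adjusted p = 0.0012, 0.0205 with an estimated correlation). The TNF receptor family member TNFRSF19 changed by -2.04 ± 0.037, NOTUM by -1.14 ± 0.037 (137 ± 8.87 against 302 ± 4.74 CPM), LGR5 by -0.65 ± 0.036 and NKD1 by -0.36 ± 0.029. AXIN2 rose by 0.35 ± 0.039 (193 ± 6.3 against 151 ± 5.29 CPM, 1.83e-10). CTNNB1 changed by -0.15 ± 0.028 and MDK by -0.26 ± 0.033 (245 ± 3.11 against 294 ± 11 CPM, 5.34e-09), and LEF1 was barely expressed (0.4 ± 0.84, 0.692). In the only library at 0.3 uM, AXIN2 was higher by 0.51, NOTUM lower (-1.52), TOP2A lower (-3.01) and CYP1A1 higher by 4.72, and the cell cycle median (-2.29) lay below all of 10000 random lists.

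**Figure D2:**
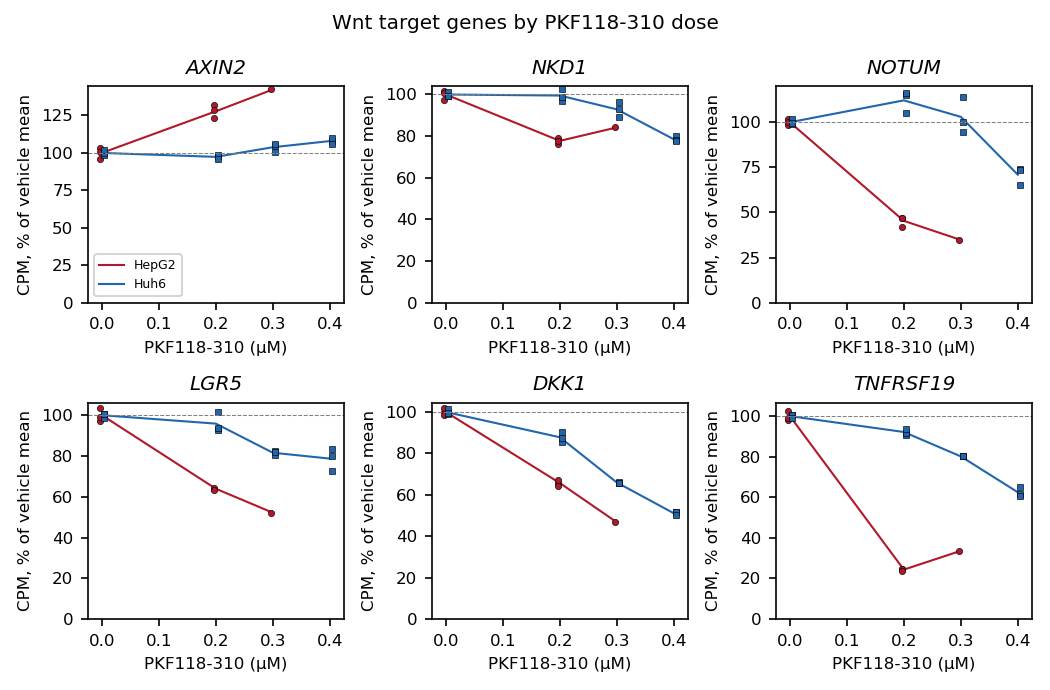
CPM of 6 Wnt/beta-catenin targets in percent of the vehicle mean (vertical) against the PKF118-310 dose in uM (horizontal), with one point per library, lines through the means, circles for HepG2 and squares for Huh6. At 0.4 uM in Huh6 and 0.2 uM in HepG2, AXIN2 is above its vehicle mean and NOTUM, NKD1 and LGR5 are below theirs, and HepG2 at 0.3 uM is a single library.

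The response to the shared 0.2 uM dose of PKF118-310 differed between the lines for 4362 genes with a more positive and 4332 with a more negative change in HepG2, of 15438 tested. The change in HepG2 was more negative for all 27 cell cycle genes (median difference -2.67, adjusted p = 1.54e-110), 19 of 21 hepatocyte genes (3.27e-27), 17 of 21 cholesterol synthesis genes (1 more positive; 18 and 1 adjusted over the list alone, 4.54e-32) and 13 of 15 endoplasmic reticulum chaperones (2 more positive, 4.17e-11). It was more positive for 12 of 16 integrated stress response genes (2 more negative, 3.33e-12).

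In Huh6, iMDK was given to ask what loss of midkine does, and NRF2 targets were prominent among the genes that rose at 10 uM. The thioredoxin reductase TXNRD1 rose by 2.4 ± 0.025 (1920 ± 14.1 against 363 ± 10.3 CPM, n = 3, adjusted p = 1.02e-45), the aldo-keto reductases AKR1B10 (5.9 ± 0.16, from 0.538 ± 0.0637 to 32.6 ± 2.86 CPM) and AKR1C1 (3.89 ± 0.12), which have close paralogues, and OSGIN1 by 3.31 ± 0.067. The neuronal microtubule protein MAP2 rose by 6.56 ± 0.13 (60.9 ± 1.46 against 0.639 ± 0.19 CPM), and EGR1 (4.05 ± 0.093), NPPB (3.98 ± 0.11), SOCS2 (3.35 ± 0.053) and GDF15 (2.02 ± 0.034) rose too. AFP fell by 1.63 ± 0.064 on the log2 scale (20.9 ± 1.92 against 64.3 ± 5.16 CPM), IGF2 by 1.79 ± 0.033, HMGA2 by 1.24 ± 0.025 and the bile acid carrier SLC10A1 by 2.42 ± 0.1. TF fell by 1.27 ± 0.029, ALB by 1.21 ± 0.24, GPC3 by 0.6 ± 0.02 and the ligand WNT8A by 2.66 ± 0.063. MDK itself fell by 0.43 ± 0.025 (319 ± 4.36 against 429 ± 11.3 CPM, 1.22e-18). In all, 3905 genes were higher and 3925 lower at 10 uM, 448 and 735 of them at least 2-fold, and 2602 and 2755 at 5 uM.

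At 10 uM, 15 of 16 NRF2 targets rose (median 1.23, adjusted p = 5.15e-72), as did all 11 heat shock genes (1.54e-14), 17 of 19 p53 targets (18 adjusted over the list alone, 1.1e-20) and 12 of 16 integrated stress response genes (3 fell, 5.04e-17). All 19 hepatocyte genes fell (1.94e-29), with 11 of 14 fetal liver genes (1 rose, 1.69e-17), 24 of 27 cell cycle genes (1 rose, 3.05e-10), 16 of 21 cholesterol synthesis genes (1 rose, 7.13e-10), 13 of 15 endoplasmic reticulum chaperones (2.82e-08) and 6 of 8 pericentral genes (7 over the list alone, 3.49e-07). Of 16 Wnt/beta-catenin targets, 13 fell and 2 rose (2.09e-05, 0.0072 with an estimated correlation). NOTUM changed by -1.36 ± 0.09, NKD1 by -0.58 ± 0.028, LEF1 by -0.41 ± 0.062, AXIN2 by -0.21 ± 0.029 and CTNNB1 by -0.07 ± 0.021. LGR5 rose by 0.18 ± 0.061 (adjusted p = 0.0143), a call lost without iMDK 10 uM replicate 2 (0.0749). MDK and its reported receptors were not called as a list (4 of 14 rose and 5 fell, or 5 and 5 over the list alone, 0.523). Ribosomal proteins (18 of 25 fell, 1 rose, 0.0124, then 0.392), metallothioneins (2 of 4 fell, 0.0419, then 0.21) and mesenchymal genes (6 of 14 rose and 6 fell, 0.024, then 0.259) passed only with the preset correlation.

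The response to iMDK grew with its dose in Huh6. AKR1B10 rose by 5.55 ± 0.16 at 5 uM and was 0.35 ± 0.082 higher at 10 uM than at 5 uM (adjusted p = 0.000956), TXNRD1 rose by 1.78 ± 0.025 and was a further 0.62 ± 0.023 higher. AFP changed by -0.94 ± 0.06 and a further -0.69 ± 0.07. At 5 uM, 15 of 16 NRF2 targets rose (3.89e-100) and 14 of 19 hepatocyte genes fell (15 fell and 1 rose adjusted over the list alone, 6.08e-20). Between the doses, 1906 genes were higher and 1838 lower at 10 uM, including all 11 heat shock genes higher (2.17e-21).

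In HepG2, iMDK at 10 uM switched on interferon-stimulated genes. The antiviral gene RSAD2 (ENSG00000134321.11, chromosome 2, 6865806 to 6898239) rose from 0 to 130 ± 5.34 CPM, at least 2420-fold (n = 3, adjusted p = 2.98e-35), and IFI44 from 0 to 42 ± 2.72 CPM, at least 779-fold. DDX60 rose by 8.81 ± 0.12 (132 ± 4.22 against 0.285 ± 0.103 CPM, 2.17e-38), OASL by 8.75 ± 0.14, IFI27 by 8.16 ± 0.12, the ubiquitin ligase HERC5 by 8.06 ± 0.11 and IFI6 by 5.43 ± 0.067 (503 ± 48.8 against 11.7 ± 1.55 CPM). Of 17 measured interferon-stimulated genes 16 rose, with a median of 3.44 (5.22e-81, 3.25e-05 with an estimated correlation). Antigen presentation rose with them, B2M by 1.15 ± 0.03 (799 ± 15 against 361 ± 11.1 CPM), HLA-B by 1.04 ± 0.037 and HLA-C by 0.75 ± 0.034. The call of the MHC class I list (11 of 13 rose, 2.54e-05) ended with an estimated correlation (0.125), and HLA genes share sequence with one another. The chemoattractant CXCL8 rose by 2.33 ± 0.072 and LIF by 1.76 ± 0.062, among 7 of 10 chemokines and cytokines that rose (1 fell, 0.000182). In Huh6 at the same dose 4 of 13 interferon-stimulated genes rose and 4 fell, and the list was not called (0.654, with median and test of opposite sign).

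Proliferation genes fell in HepG2 with 10 uM iMDK. TOP2A changed by -1.97 ± 0.035 (183 ± 0.38 against 719 ± 21.6 CPM), MKI67 by -1.84 ± 0.05, the helicase subunit MCM2 by -1.83 ± 0.041 and UHRF1 by -2.07 ± 0.056, and all 27 cell cycle genes fell (median -1.54, adjusted p = 6e-84). SLC7A11 (2.22 ± 0.079), TXNRD1 (1.73 ± 0.03) and GCLM (1.63 ± 0.038) were among 12 of 15 NRF2 targets that rose (with 1 lower over the list alone, 4.78e-21), and ATF3 (2.57 ± 0.056) among 11 of 15 integrated stress response genes (2 fell, or 3 over the list alone, 9.55e-13). Among p53 targets 12 of 19 rose and 5 fell (2.54e-05), with CDKN1A at 1.25 ± 0.031. Unlike in Huh6, 17 of 20 cholesterol synthesis genes rose (1 fell, 6.95e-09), and endoplasmic reticulum chaperones rose (11 of 15, with 4 lower, 0.00279, 0.126 with an estimated correlation), with HSPA5 at 0.63 ± 0.028. ALB changed by -1.06 ± 0.036, AFP by -0.98 ± 0.035 (1760 ± 7.47 against 3450 ± 83.9 CPM), GPC3 by -0.3 ± 0.029 and MDK by -0.31 ± 0.033 (237 ± 7.06 against 294 ± 11 CPM, 2.29e-10). In all, 4222 genes were higher and 4207 lower, 1117 and 695 of them at least 2-fold.

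Wnt/beta-catenin targets fell in HepG2 with iMDK, 12 of 15 with 0 higher (median -0.56, adjusted p = 5.19e-10, 0.000965 with an estimated correlation). DKK1 changed by -1.86 ± 0.033 (175 ± 6.88 against 635 ± 11.2 CPM) and TNFRSF19 by -1.09 ± 0.034. LGR5 changed by -0.7 ± 0.036, NOTUM by -0.57 ± 0.036, NKD1 by -0.51 ± 0.029, AXIN2 by -0.4 ± 0.04 and CTNNB1 by -0.32 ± 0.028, while LEF1 was too low to judge (0.69 ± 0.81, 0.491). MDK with its receptors was not called as a list (4 of 13 rose and 6 fell, 0.67), although the co-receptor SDC4 rose by 1.27 ± 0.033. Further calls that ended with an estimated correlation were those of ribosomal proteins (22 of 25 fell, 6.71e-06, then 0.299), fetal liver genes (10 of 14 fell, 2 rose, 0.000221, then 0.145) and hepatocyte genes (14 of 22 fell, 5 rose, 0.00279, then 0.343). The same was true of pericentral genes (6 of 10 fell, 1 rose, 0.00878, then 0.0612) and metallothioneins (2 of 5 rose and 2 fell, 0.0365, then 0.314, with a median of -0.79 against an upward test). Checkpoint genes (3 of 6 rose, 0.407) and macrophage identity genes (3 of 8 rose and 2 fell, 0.987) were not called.

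At 5 uM iMDK, HepG2 already had 3588 genes higher and 3724 lower, and RSAD2 reached 53 ± 1.82 CPM, at least 981-fold. The interferon list had a median of 2.66 (16 of 17 rose, adjusted p = 5.3e-79), the cell cycle list a median of -1.27 (27 of 27 fell, 2.38e-96), and 18 of 20 cholesterol synthesis genes rose (1 fell, 5.37e-19). Between 10 and 5 uM, 1005 genes were higher and 1072 lower. RSAD2 was 1.3 ± 0.059 higher, IFI27 0.91 ± 0.053 and DDX60 0.83 ± 0.049, and TOP2A differed by -0.26 ± 0.035. Between the doses 14 interferon-stimulated genes were higher (15 over the list alone, 4.56e-75) and 7 MHC class I genes (8 over the list alone, 3.54e-11), whereas 9 cholesterol synthesis genes were lower and 1 higher (11 and 1 over the list alone, 3.55e-05, 0.0685 with an estimated correlation).

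**Figure D3:**
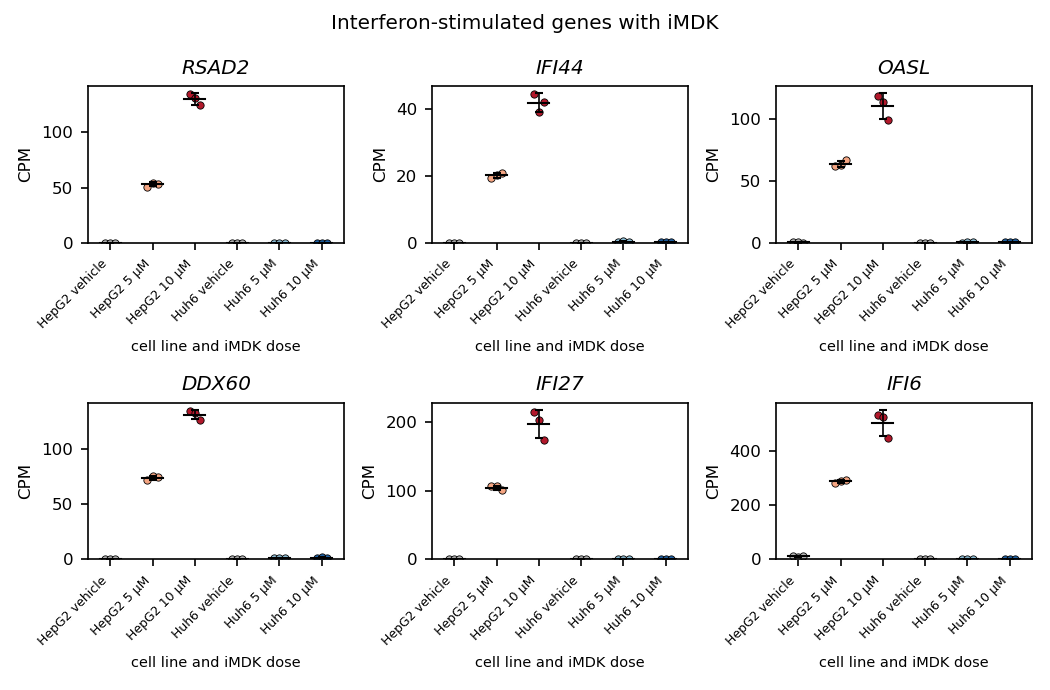
CPM of 6 interferon-stimulated genes (vertical) in HepG2 and Huh6 libraries with vehicle, 5 uM or 10 uM iMDK (horizontal), with one point per library, lines for means and bars for SD (n = 3). In HepG2 RSAD2 went from 0 to 53 ± 1.82 and 130 ± 5.34 CPM.

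The response to 10 uM iMDK differed between the lines for 3235 genes with a more positive and 3187 with a more negative change in HepG2, of 15414 tested. Interferon-stimulated genes were more positive in HepG2 (14 of 17, median difference 3.76, adjusted p = 3.32e-15), as were cholesterol synthesis genes (19 of 21, or 20 over the list alone, 1.54e-36), endoplasmic reticulum chaperones (14 of 15, 9.89e-19) and hepatocyte genes (16 of 21, 1 more negative, 5.7e-12). Cell cycle genes (27 of 27, median difference -1.16, 3.88e-84), NRF2 targets (10 of 16 with 2 more positive, or 11 and 3 over the list alone, 2.39e-13) and heat shock genes (10 of 11, 2.22e-07) were more negative. Within a line, both inhibitors moved many of the same genes. In Huh6, 0.4 uM PKF118-310 and 10 uM iMDK shared 2843 higher and 2807 lower genes (1130 and 1090 if independent) against 402 in opposite directions. In HepG2, 0.2 uM PKF118-310 and 10 uM iMDK shared 3079 and 3242 (1450 and 1410 if independent) against 729. Both comparisons use the same 3 vehicle libraries, so part of the excess may come from these. The Pearson correlation of the log2 fold changes was 0.73 in Huh6 and 0.67 in HepG2. Simulated unchanged groups gave 0.01 and 0.04, but they were drawn around the mean of the same vehicle libraries. The error of those libraries is absent from them, so they cannot show how much of the correlation comes from shared controls.

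Libraries of THP-1 macrophages sorted after co-culture held transcripts that are typical of the tumour cells. With untreated HepG2, the apolipoprotein APOB reached 359 ± 73.9 CPM from 0 in monoculture (at least 5890-fold), ALB 904 ± 87.9 CPM and the insulin-like growth factor binding protein IGFBP1 285 ± 49.9 CPM from 0. The estimated share of tumour reads was 9.77 ± 0.38% (SD, n = 3) with untreated HepG2, 5.54 ± 0.94% with HepG2 given 5 uM iMDK and 3.02 ± 1.3% with 10 uM. Over all tumour-specific genes it was 5.12, 3.35 and 1.95%, the lower share below. With Huh6 it was 0.774 ± 0.67%, 0.182 ± 0.03% and 0.152 ± 0.027%, or 0.64, 0.151 and 0.134% over all such genes. Each exact permutation test between a co-culture and its reference gave p = 0.1, the smallest possible. Because this share differs between the groups compared, genes of the tumour cells are set apart in the THP-1 comparisons, and the value after subtraction of the estimated tumour reads is given where it ended the call of a gene named by the rule, other than APOB with untreated HepG2, whose change is 0 then.

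**Figure D4:**
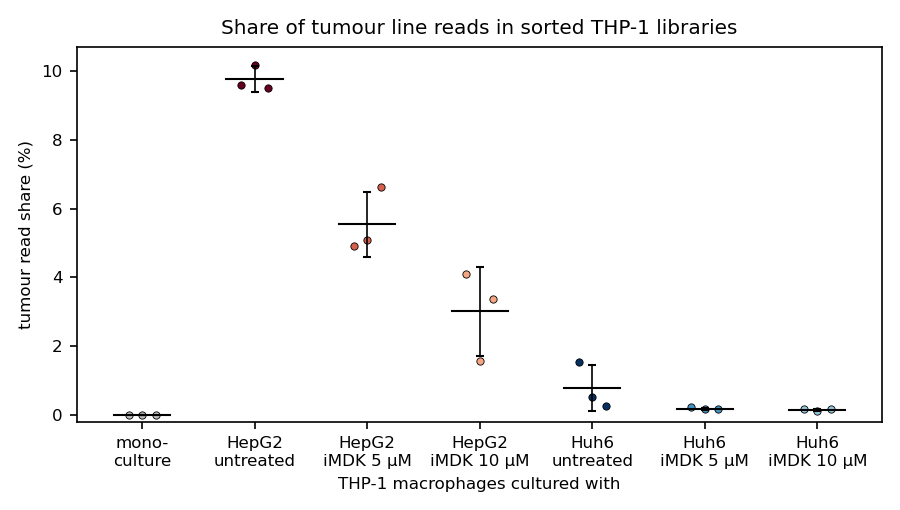
Estimated share of tumour reads in percent (vertical) in each THP-1 library (points) by culture (horizontal), with means and SD (n = 3). The share fell from 9.77% with untreated HepG2 to 3.02% with 10 uM iMDK, and was 1.53% at most with Huh6.

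Macrophages with untreated HepG2 were compared with monoculture to ask what tumour contact changes. Some macrophage genes that HepG2 hardly expresses rose and others fell. Among those that rose was the inhibitory Fc receptor FCGR2B (2.65 ± 0.33, 17.1 ± 1.13 against 2.73 ± 0.348 CPM, n = 3, adjusted p = 3.72e-06), which has close paralogues. The chemokines CCL18 (1.79 ± 0.42, 0.00318) and CCL24 (1.06 ± 0.21, 24.5 ± 3.78 against 11.7 ± 2.3 CPM, 0.000871) also rose. The glycoprotein GPNMB (0.88 ± 0.19, 2750 ± 653 against 1500 ± 245 CPM, 0.00185) and complement factor D, CFD (1.21 ± 0.19), which stood at 1.58 and 9.5 CPM in HepG2, rose too. The membrane scaffold EPB41L3 changed by -2.22 ± 0.12 (10.5 ± 0.827 against 48.8 ± 3.39 CPM, 1.48e-11), the aryl hydrocarbon receptor target CYP1B1 by -2.04 ± 0.17 (13 ± 1.75 against 53.5 ± 8.46 CPM). The IgA receptor FCAR changed by -2.41 ± 0.42 and the pattern receptor TLR2 by -0.88 ± 0.16. The monocyte marker CD14 fell by 0.41 ± 0.083 on the log2 scale (0.00107), a call that ended after subtraction (-0.2, 0.0814) but not at the lower share (0.0208). The cytokine IL1B fell by 2.18 ± 0.61 (11.3 ± 5.04 against 51.3 ± 41.1 CPM, 0.012), a call lost without monoculture replicate 1 (0.149) or untreated co-culture replicate 2 (0.0629). MDK rose by 0.52 ± 0.11 (162 ± 19.1 against 113 ± 11.7 CPM, 0.00186, and 0.00888 after subtraction), and its receptor LRP1 by 0.42 ± 0.12 (0.0148, lost without untreated co-culture replicate 3, 0.0908). HepG2 itself expresses MDK above the level of these macrophage libraries. Single HepG2 genes lay on both sides of the subtracted share, such as APOB at 5.74% and IGFBP1 at 21.3%. HepG2 RNA is therefore not excluded as a source of the MDK rise. In all, 1853 genes were higher and 1501 lower, 1002 and 174 of them at least 2-fold, and 5118 passed with the replicate number as a block. After subtraction 1518 were higher and 1976 lower, but 1547 and 1327 at the lower share, so the direction of the balance depends on the share assumed. With only genes no higher in HepG2 it was 465 and 1003.

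By gene list, all 5 metallothioneins fell with HepG2 (median -2.22, adjusted p = 1.87e-08, 0.0424 with an estimated correlation), with MT1G at -2.39 ± 0.32. Hypoxia genes rose (11 of 16, median 0.91, 1.83e-05, then 0.389). The carbonic anhydrase CA9 rose by 6.36 ± 0.87 (from 2 to 190 counts, with a counting interval of 26.9 to 821 for the ratio), the peptide ADM rose by 2.42 ± 0.44 and BNIP3 by 1.97 ± 0.25. Integrated stress response genes fell (7 of 16 with 1 higher, 0.000235, then 0.133), with CHAC1 at -1.5 ± 0.12 (13.8 ± 1.19 against 39.1 ± 2.4 CPM, 1.22e-08) and the amino acid carrier SLC7A5 at -1.22 ± 0.13. So did aryl hydrocarbon receptor targets (2 of 4 fell and 1 rose, 0.00333, then 0.0588). The p53 targets were called higher (8 of 19 rose, or 9 over the list alone, and 1 fell, 0.02, then 0.207), which ended after subtraction (0.284, with the opposite sign). The MHC class II list was not called (4 of 7 rose, 0.0644), but passed with the replicate number as a block (0.0366), as did ribosomal proteins (0.322, then 0.0104 with the block), and CD74 rose by 0.58 ± 0.1. HepG2 also expresses CD74 (226 CPM), and its rise would need a share of 34.7%, against an estimated 9.77%. A part from HepG2 RNA is not excluded. All 18 measured hepatoblastoma markers rose (1.17e-83).

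Lists of macrophage activation were not called in either direction with HepG2, although members of several changed both ways. Inflammatory genes (1 of 9 fell, or 1 rose and 1 fell over the list alone, adjusted p = 0.933), alternative activation genes (4 of 19 rose and 4 fell, or 5 and 5, 0.895) and lipid-associated genes (4 of 15 rose, 0.524) were not called. The same held for NF-kappaB feedback genes (1 of 12 rose and 4 fell, or 1 and 5, 0.358), phagocytosis genes (5 of 15 rose and 3 fell, or 6 and 3, 0.511), matrix genes (2 of 9 rose and 4 fell, 0.358) and for macrophage identity genes (1 of 15 rose and 2 fell, or 1 and 3, 0.933). Checkpoint genes (2 of 10 rose and 1 fell, or 4 and 2, 0.572), chemokines and cytokines (3 of 13 rose and 3 fell, 0.933), MHC class I genes (1 of 13 rose and 1 fell, 0.546) and interferon-stimulated genes (1 of 18 rose, 0.558) were not called. Neither were the scavenger receptor CD163 (-0.66 ± 0.25, 0.0595), TNF (-1.24 ± 0.55, 0.117), the costimulatory gene CD86 (0.28 ± 0.1, 0.0505), CD274 (1.17 ± 0.69, 0.255) or HLA-DRA (0.47 ± 0.81, 0.733). With the replicate number as a block, CD163 (1.89e-05), TNF (6.54e-05) and CD86 (0.0171) passed.

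Untreated Huh6 changed fewer genes in macrophages, 205 higher and 78 lower, with 927 called when the replicate number was a block. After subtraction 29 were higher and 37 lower (50 and 53 at the lower share), and 13 and 34 with only genes no higher in Huh6. Of the lists that fell with HepG2, 2 were called with Huh6. Integrated stress response genes fell (9 of 16, or 11 over the list alone, median -0.46, adjusted p = 4.65e-23, 0.000395 with an estimated correlation), with SLC7A5 at -0.98 ± 0.13 (200 ± 17.5 against 396 ± 63.6 CPM, n = 3, 0.000176), CHAC1 at -0.89 ± 0.12, TRIB3 at -1.01 ± 0.14 and the serine synthesis gene PSAT1 at -0.78 ± 0.1. Metallothioneins fell (3 of 5, or 5 over the list alone, 2.05e-12, then 0.00602). EPB41L3 changed by -1 ± 0.11 (24.4 ± 1.91 against 48.8 ± 3.39 CPM, 1.92e-05). EGR1 rose by 1.21 ± 0.18 (0.000403) and the interferon-induced GTPase GBP2 by 1.02 ± 0.19 (0.00499). Cell cycle genes were higher as a list (4 of 27 rose, or 24 over the list alone, median 0.55, 7.08e-23, then 0.123). Among them MKI67 rose by 0.78 ± 0.18 (120 ± 11.5 against 69.4 ± 17.9 CPM, 0.024), a call lost after subtraction (0.78, 0.11) though its size stayed, and without monoculture replicate 1, untreated co-culture replicate 1 or replicate 2 (0.0903 to 0.186).

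Other calls with Huh6 rested on tumour genes or on the preset correlation. APOB (38.4 ± 28.6 CPM, at least 631-fold, adjusted p = 1.92e-05, 0.423 after subtraction), EPCAM (6.59 ± 0.68, too low to test after subtraction) and the keratin KRT8 (5.66 ± 0.5) rose with 9 of 18 hepatoblastoma markers (14 over the list alone, 9.1e-49). Cholesterol synthesis genes (2 of 20 rose, or 3, 2.41e-05, then 0.24), MHC class II genes (0 of 7, or 2, 0.0115, then 0.24) and mitochondrially encoded genes (0 of 13, 0.000252, then 0.298) passed as lists only with the preset correlation. With the replicate number as a block, aryl hydrocarbon receptor targets (0.0682, then 0.00633), chemokines and cytokines (0.109, then 0.00984), matrix genes (0.15, then 0.0475) and macrophage identity genes (0.283, then 0.0306) passed too. CD163 (0.01 ± 0.24, 0.995), TNF (-0.75 ± 0.54, 0.719), IL1B (-1.52 ± 0.59, 0.276), CD86 (0.13 ± 0.1, 0.748), CD274 (-0.42 ± 0.83, 0.934), HLA-DRA (1.02 ± 0.77, 0.744) and LRP1 (0.14 ± 0.12, 0.789) were not called, though IL1B (1.39e-05) and TNF (0.0174) passed with the block.

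Of the genes called with Huh6, 147 higher and 61 lower were called in the same direction with HepG2, against 24.5 and 7.55 if independent, and 1 in the opposite direction. Both comparisons share the monoculture libraries and both co-cultures held tumour reads, so part of the excess may come from these. The overlap was not recounted after subtraction. The Pearson correlation of the log2 fold changes was 0.64. Simulated unchanged groups gave 0.03, but as they were drawn around the monoculture mean they lack the error of those libraries. They cannot show how much of the correlation comes from shared controls. Directly between the untreated co-cultures, 1415 genes were higher and 1171 lower with HepG2 than with Huh6, and 4505 passed with the replicate number as a block. After subtraction 1201 were higher and 1763 lower, but 1182 and 1005 at the lower share, and 235 and 456 with only genes no higher in the tumour line. Hypoxia genes were higher with HepG2 (11 of 16, or 12 over the list alone, adjusted p = 3.21e-05, 0.643 with an estimated correlation) and cell cycle genes lower (16 of 27, or 18, 7.38e-09, then 0.653). Metallothioneins (3 of 5 lower, or 5, 0.0157, then 0.643) and aryl hydrocarbon receptor targets (1 of 4 lower, 0.029, then 0.273) were lower as well, and 15 of 18 hepatoblastoma markers higher (16 over the list alone, 1.94e-61).

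Pretreatment of HepG2 with 10 uM iMDK was compared with untreated co-culture to ask whether tumour midkine acts on macrophages. In all, 100 genes were higher and 418 lower, against 709 and 298 after subtraction, but 182 and 290 at the lower share. With only genes no higher in HepG2, 16 were higher and 7 lower, and 467 and 140 with the replicate number as a block. The sialic acid receptor SIGLEC1 rose by 0.81 ± 0.15 (112 ± 20.5 against 63.8 ± 7.12 CPM, n = 3, adjusted p = 0.00323, 0.00867 after subtraction), the tryptophan dioxygenase TDO2 by 0.71 ± 0.13 (438 ± 31.1 against 267 ± 51 CPM, 0.004) and the transcriptional repressor HIC1 by 1.21 ± 0.23 (0.00422). FCGR2B changed by -1.22 ± 0.31 (7.29 ± 3.11 against 17.1 ± 1.13 CPM, 0.0269), but not without untreated replicates 1 or 2 or iMDK 10 uM replicates 2 or 3 (0.0839 to 0.142), nor with only genes no higher in the tumour line (0.113). The interferon-stimulated genes OASL (2.32 ± 0.52, 0.0123) and IFI44 (1.04 ± 0.27, 0.0354) rose, calls lost without untreated replicates 1 or 3 or iMDK 10 uM replicate 3, and for IFI44 also untreated replicate 2 or iMDK 10 uM replicate 1 (0.0501 to 0.16). After subtraction IFI44 was not called (0.63, 0.206) and OASL was too low to test. With only the groups compared, and without all libraries numbered 1, neither IFI44 (0.0852 and 0.0963) nor OASL (0.0502 and 0.0968) was called. The interferon list was called (2 of 18 rose, or 10 over the list alone, 2.08e-07), but not with an estimated correlation (0.187) or after subtraction (0.847), and in HepG2 with 10 uM iMDK these genes stood at 111 and 42 CPM.

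Liver genes that HepG2 expresses were prominent among the lower genes. The fibrinogen chains FGA (-2.25 ± 0.3, 28.5 ± 15.5 against 136 ± 11.4 CPM, adjusted p = 0.000362) and FGB (-2.23 ± 0.31), APOC3 (-3.09 ± 0.45) and AGXT (-2.9 ± 0.53) fell with 15 of 18 hepatoblastoma markers (17 over the list alone, 1.04e-36). Hypoxia genes fell (3 of 16, or 10 over the list alone, 2.08e-07, 0.361 with an estimated correlation), with CA9 at -2.97 ± 0.62 (0.00778) and BNIP3 at -1.07 ± 0.24 (0.0144, -0.95 with 0.0638 after subtraction but 0.0322 at the lower share, and 0.101 with only the groups compared), calls lost without untreated replicate 2 or iMDK 10 uM replicates 2 or 3 (0.0511 to 0.0914). Cell cycle genes (0 of 27, 0.000221, then 0.897) and p53 targets (1 of 19 fell, 0.0479, then 0.361, and 0.405 with the opposite sign after subtraction) passed as lists only with the preset correlation. CD163 (0.07 ± 0.25, 0.933), IL1B (0.29 ± 0.62, 0.873), TNF (0.17 ± 0.58, 0.924), CD86 (0 ± 0.1, 0.988), CD274 (-1.33 ± 0.73, 0.388), HLA-DRA (0.5 ± 0.75, 0.807) and LRP1 (0 ± 0.12, 1) were not called. With the replicate number as a block 1802 genes passed, and ribosomal proteins (0.0882, then 0.000481), endoplasmic reticulum chaperones (0.107, then 0.012), checkpoint genes (0.165, then 0.0108) and lipid-associated genes (0.26, then 0.012) passed as lists.

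**Figure D5:**
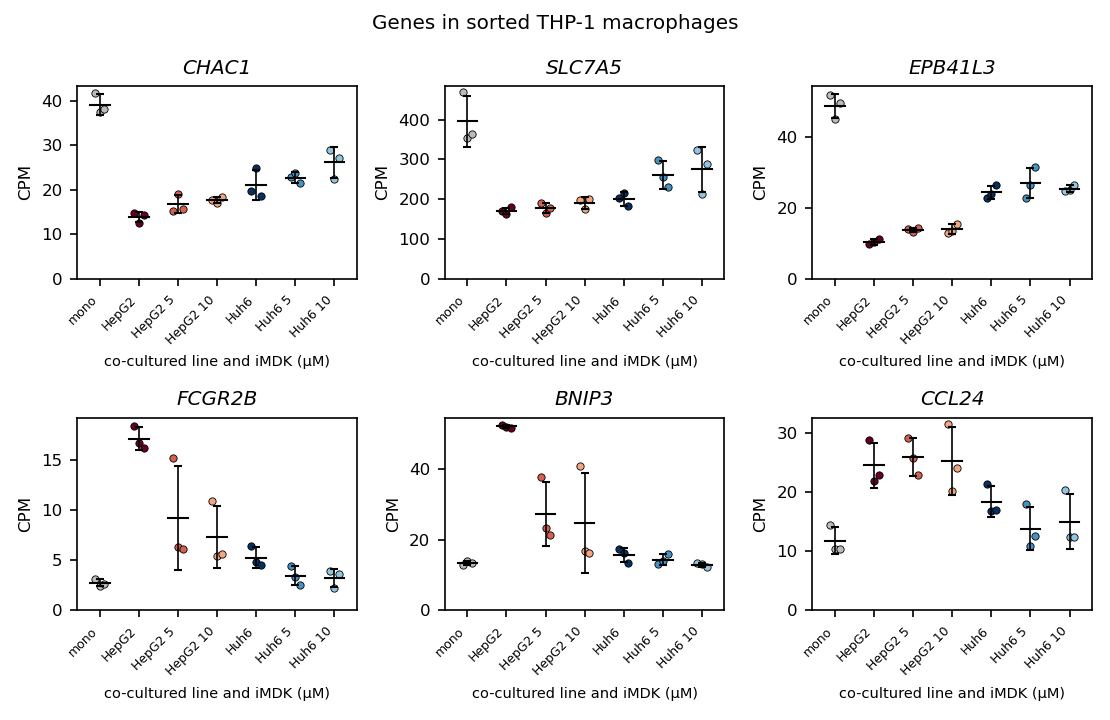
CPM of 6 genes (vertical) in THP-1 libraries of 7 cultures (horizontal), with one point per library, lines for means and bars for SD (n = 3). EPB41L3 fell from 48.8 ± 3.39 CPM in monoculture to 10.5 ± 0.827 with untreated HepG2 and 24.4 ± 1.91 with untreated Huh6.

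After HepG2 had received 5 uM iMDK, 3 genes were higher in macrophages and 11 lower, against 330 and 128 after subtraction, but 34 and 66 at the lower share. SIGLEC1 rose by 0.94 ± 0.15 (122 ± 15.5 against 63.8 ± 7.12 CPM, n = 3, adjusted p = 0.0184), a call lost without untreated replicate 1 (0.0511) or 2 (0.128) or iMDK 5 uM replicate 3 (0.0594). The others, outside the naming rule and chosen after their values were seen, were MLXIPL (0.58, 0.0309) and PTPN7 (0.44, 0.0459). With the replicate number as a block 614 genes passed. The interferon list was higher (0 of 18 called, 5 over the list alone, 7.99e-10, 0.135 with an estimated correlation, 0.842 after subtraction, 0.0402 at the lower share), and hypoxia genes (0 of 16 called, 11 over the list alone, 9.96e-11, then 0.159) and hepatoblastoma markers (0 of 18 called, 9 over the list alone, 5.15e-14, then 0.158, 0.127 after subtraction, 1.09e-07 at the lower share) were lower.

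Few genes were called in macrophages after pretreatment of Huh6. At 10 uM, the scavenger receptor MARCO fell by 0.91 ± 0.16 on the log2 scale (4.98 ± 0.347 against 9.33 ± 0.0932 CPM, n = 3, adjusted p = 0.0369), and not without untreated replicates 1 or 2 or any iMDK 10 uM replicate (0.0723 to 0.414), nor after subtraction (-0.92, 0.175). APOB (-2.92 ± 0.51, 0.0358) was lost without untreated replicate 1 or any iMDK 10 uM replicate (0.0914 to 0.389), EPCAM (-2.3 ± 0.43, 0.0429) without the same libraries or untreated replicate 2 (0.0521 to 0.899), and APOA1 (-2.52 ± 0.35, 0.00507) without iMDK 10 uM replicates 1 or 3 (0.0702 to 0.0768). After subtraction APOB (-4.53, 1) and APOA1 (-2.15, 0.251, but 0.0109 at the lower share) were not called and EPCAM was too low to test. Of 9 genes called, 8 were lower, and the only higher gene, the chaperone CLGN (1.7, 0.0108), was chosen after its value was seen. At 5 uM, CLGN was higher (1.83, 0.00683) and APOA1 lower (-2.01, 0.0377), and 21 genes passed with the replicate number as a block. After subtraction 1 gene was higher and 0 lower at either dose (1 and 1 at 10 uM at the lower share), so APOA1 was no longer called at 5 uM. Integrated stress response genes were higher as a list at 5 uM (0 of 16 called, 5 over the list alone, 7.03e-09, 0.0189 with an estimated correlation) and at 10 uM (0 called, 4 over the list alone, median 0.2, 1.4e-08, then 0.0223). Hepatoblastoma markers were lower at 10 uM (3 of 18, or 13 over the list alone, 5.6e-37, 0.0584 after subtraction, 0.000131 at the lower share). Alternative activation genes were lower as a list at 10 uM (0 of 19 called, 0.042, then 0.194) and at 5 uM only with the block (0.0817, then 0.0066). CD163 (-0.7 ± 0.25, 0.634), IL1B (0.39 ± 0.59, 1), TNF (0.39 ± 0.54, 1), CD274 (1.45 ± 0.75, 1), CD86 (0.01 ± 0.1, 1), HLA-DRA (-1.1 ± 0.78, 1) and LRP1 (0.04 ± 0.12, 1) were not called at 10 uM. Between the co-cultures, the macrophage response to 10 uM iMDK differed for 1 gene, SIGLEC1 (1.29 ± 0.18 more positive with HepG2, 0.0469), of 14999 tested. The call was lost with RLE scaling (0.0535) and without any of 7 libraries left out in turn (0.0531 to 0.273).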

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

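The tests of genes below were planned, and of the tests of explanations that of interferon transcripts in HepG2 was written before its result was seen, while all other tests of explanations and the regroupings of libraries were chosen only afterwards.

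The response to 0.2 uM PKF118-310 differed between HepG2 and Huh6 for 8694 genes. Regrouping the libraries within each line 100 times gave as many genes in 1 of the 100, the real grouping. The highest other grouping gave 8576 genes and kept the real HepG2 groups while mixing those of Huh6, so the count follows the response of HepG2 and cannot test a difference between the lines. The log2 change in HepG2 minus that in Huh6 was 10.99 ± 1.7 for MMP3 (adjusted p = 2.62e-07), 8.49 ± 0.69 for IGFN1, 7.43 ± 0.81 for ANXA1, 6.73 ± 0.23 for the phosphodiesterase PDE2A (2.22e-28) and 6.7 ± 0.92 for CAPN13. It was -4.61 ± 0.21 for the collagen COL2A1 (1e-23), -4.68 ± 1.3 for WNT8A, -4.59 ± 1.2 for the lectin MBL2, -4.5 ± 1.5 for CLMP and -4.35 ± 1.5 for CFAP221. MMP3, IGFN1 and MBL2 were too low to test in Huh6 alone (10.75, 8.07 and -2.15 in HepG2), and WNT8A, CLMP and CFAP221 in HepG2 alone (-0.3, -0.04 and 0 in Huh6), so these sizes rest on low counts. The call of MBL2 was lost without Huh6 PKF118-310 0.2 uM replicate 2 (0.0753) and that of CFAP221 without HepG2 vehicle replicate 1 (0.0575).

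The response to 10 uM iMDK differed between the lines for 6422 genes. As many genes came from 2 of 100 groupings, the real one and one with 8536 genes that exchanged treated and vehicle libraries in Huh6 alone, so that the responses of both lines add up, and this count cannot test a difference between the lines either. The difference was 8.32 ± 0.59 for IFI27 (adjusted p = 7.07e-17), 7.19 ± 0.9 for the phosphatase ALPI, 6.72 ± 1.1 for HERC5, 6.62 ± 1.8 for OAS1 and 5.93 ± 0.18 for TUSC3 (3.59e-31). It was -4.64 ± 0.5 for the myosin light chain MYL7, -4.52 ± 0.17 for AKR1B10 (1.68e-27), -3.53 ± 0.39 for the corepressor TBL1X, -3.52 ± 1.4 for NALF2 (0.0459) and -3.15 ± 0.62 for PALMD. HERC5, OAS1, NALF2 and PALMD were too low to test in Huh6 alone (8.06, 3.44, 0.3 and -0.99 in HepG2), so these sizes rest on low counts. OAS1 was lost without Huh6 vehicle replicate 3 (3.43, 1). NALF2 was lost with DESeq2 (-2.87, 0.0866), all libraries (0.0511) or no filter (0.0905), and without HepG2 vehicle replicate 1, HepG2 iMDK replicates 1 or 2, any Huh6 vehicle replicate or Huh6 iMDK replicate 3 (0.0505 to 0.16).

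In macrophages, the response to 10 uM iMDK differed between the co-cultures for 1 gene, SIGLEC1, by 1.29 ± 0.18 (adjusted p = 0.0469). Of 100 groupings 12 gave as many genes, with 347 in the highest other, so chance is not excluded. Such groupings can exchange treated and untreated libraries within a co-culture, so a high count can follow the response of either co-culture. What gave the 347 genes was not tested. The call was lost with RLE scaling (0.0535) and without HepG2 untreated replicates 1 (0.105) or 2 (0.273), Huh6 untreated replicates 1 (0.0531), 2 (0.19) or 3 (0.233), or Huh6 iMDK 10 uM replicates 1 (0.115) or 3 (0.25).

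Interferon-stimulated genes rose in HepG2 with iMDK, by a median of 3.44 at 10 uM. Scaling is argued against, since a factor common to a library cancels in the list's median minus that of all genes, which was 3.42, against at most 0.51 for 10000 random lists of like expression. Macrophage RNA was already unlikely by design, since no co-culture with macrophages is described for these HepG2 libraries, so its share is no further test. Over 120 abundant macrophage genes, the share of a macrophage profile in them had a median of 0.0225% (quartiles 0 and 0.198). The 16 risen interferon-stimulated genes would need at least 16.1% and a median of 639% of a monoculture profile, in which some of them were barely expressed. Interferon made by the HepG2 cells was in line with the counts of 21 type I and type III interferon genes, which had 50 counts in the 3 libraries at 10 uM (36 of IFNL1, 8 of IFNL2, 4 of IFNB1 and 2 of IFNL3), 23 at 5 uM and 0 with vehicle (exact binomial p = 2.33e-15, counting error only), with IFNL2 and IFNL3 being close paralogues. Huh6 had 16 such counts with vehicle and 10 with 10 uM iMDK, and why iMDK would raise them in HepG2 was not tested.

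THP-1 libraries from the HepG2 co-culture held transcripts of HepG2 although the cells had been sorted. HepG2 RNA, from cells, fragments or uptake, is consistent with the rise of 112 of 112 abundant HepG2 genes that monoculture lacks, with APOB at 359, ALB at 904 and IGFBP1 at 285 CPM in these macrophage libraries and 0, 0.102 and 0 CPM in monoculture. Neither the markers nor the purity of the sort are given in the sources used here, so whether separate HepG2 cells remained is not known. Of 244 higher genes under 1 CPM in HepG2, 237 would need a share above 100% of the HepG2 vehicle profile, which HepG2 RNA of that profile cannot supply. Choosing genes so low in HepG2 nearly fixes this count. It therefore does not test HepG2 RNA for other genes, or for genes that co-culture may have induced in HepG2. For hypoxia genes HepG2 RNA cannot be told apart from induction in macrophages. The 11 risen members would need a median share of 27.9% (6.05 to 169). This lies above the middle range of abundant HepG2 genes (3.45 to 7.96%) but under 100%. Monoculture itself has BNIP3 at 13.3 CPM, and co-culture may change the HepG2 cells' own hypoxia genes. Dilution by HepG2 reads can lower a gene's log2 value by no more than 0.16. The 1098 lower genes that HepG2 expresses no higher had a median of -0.46 (quartiles -0.71 and -0.33). This median did not clear the distance set for excluding dilution (the interquartile range of 0.38). Still, 769 of these genes lay below the bound of -0.16 by more than 2 SE, a count made after the result was seen. For these 769 the values argue against dilution alone, while for the others dilution cannot be told apart.

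With PKF118-310, AXIN2 rose in HepG2 while NOTUM, NKD1 and LGR5 fell. AXIN2 ranged from 0.32 ± 0.042, without HepG2 vehicle replicate 1, to 0.38 over the alternatives. RLE scaling (0.35) hardly moved any gene (10445 called against 10455), so it cannot test whether the rise of AXIN2 itself comes from scaling. A factor common to a library moves all genes alike, however. The gap at 0.2 uM between AXIN2 (0.35) and NOTUM (-1.14) or NKD1 (-0.36) therefore argues against scaling as the source of that gap. A shared fall of the targets, with AXIN2 as an exception, cannot be told apart. At 0.2 uM 2 others rose, CCND1 (0.14) and MYC (0.31). Both were lower in the single 0.3 uM library (-0.12 and -0.23), a condition set after these values were seen. A candidate explanation is that the inhibitor separates targets by their dependence on beta-catenin or adds other inputs to some of them, such as the stress responses seen at the same doses. These could not be separated with the groups at hand and were not tested.

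The other splits of 3 against 3 libraries (10 per comparison) are too few for a share under 0.05. In the comparisons of treated with vehicle tumour cells or of doses, the real split gave 337 to 10455 genes and the highest other 0, or 1 for Huh6 at 0.2 uM PKF118-310. For macrophages with untreated HepG2, untreated Huh6, iMDK 5 uM Huh6 and iMDK 10 uM Huh6 the real splits gave 3354, 283, 2 and 9 genes and the highest other 0. Between the untreated co-cultures these were 2586 and 1. With iMDK-treated HepG2, 2 of the 10 splits gave as many genes, with 14 against 40 at 5 uM and 518 against 809 at 10 uM. The higher counts came from splits that keep at least 1 pair of same-numbered libraries on the same side, and among the 4 splits that part all 3 pairs, as the real one does, the highest other gave 0. This points to the pairing of the libraries by replicate number.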

How the results depend on the processing

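Alternatives called subtraction at the lower share, only genes no higher in the tumour line, without all libraries numbered 1, and the replicate block with only genes no higher were chosen after seeing the data, and the others before. Depth sets limits: 3 counts equal 0.15 to 0.238 CPM per library, and HLA-DRA and CD274 lay near that in THP-1 monoculture (0.241 and 0.242 CPM). In the tumour lines no alternative moved a count of genes by over 1.5 times except leaving out 1 library for Huh6 at 0.2 uM PKF118-310, with 215 genes without vehicle replicate 3 and 216 without PKF118-310 replicate 1 against 337. In THP-1 the counts of genes depended on the processing, and where no reason is given the cause was not tested.

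For macrophages with untreated HepG2 (3354 genes), the count was 1468 with only genes no higher in the tumour line, where fewer genes are tested, and 5118 with the replicate block. With untreated Huh6 (283) it was 47 with only genes no higher, 927 with the block, 689 with no filter on low counts, 66 with tumour reads subtracted, 103 at the lower share and 81 without all libraries numbered 1. With HepG2 given 5 uM iMDK (14) it was 4 with only genes no higher, 614 with the block, 211 with the block and only genes no higher, 320 with no filter, 458 with tumour reads subtracted, 100 at the lower share, 191 without all libraries numbered 1, 148 with DESeq2 and 52 with only the groups compared. With HepG2 given 10 uM iMDK (518) it was 23 with only genes no higher, 1802 with the block, 854 with no filter, 1007 with tumour reads subtracted and 293 with only the groups compared. Subtraction takes more reads from the untreated group, whose share is larger, and can add calls by itself.

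With Huh6 given 5 uM iMDK (2 genes by edgeR, 581 at an unadjusted p under 0.05), the count was 0 with only genes no higher, with only the groups compared and without all libraries numbered 1, 1 with tumour reads subtracted at either share and with the block and only genes no higher, 21 with the block, 111 with no filter and 20 with DESeq2. With Huh6 given 10 uM iMDK (9 by edgeR, 738 at an unadjusted p under 0.05), it was 0 with only genes no higher, with only the groups compared and without all libraries numbered 1, 1 with tumour reads subtracted, 2 at the lower share, 5 with the block and only genes no higher, 75 with the block, 167 with no filter and 44 with DESeq2. Between the untreated co-cultures (2586) it was 691 with only genes no higher, 4505 with the block and 1693 with both. The difference between co-cultures in the response to 10 uM iMDK (1 by edgeR, 981 at an unadjusted p under 0.05) gave 0 with RLE scaling, 5 with all libraries, 11 with the block, 12 with DESeq2, 19 without all libraries numbered 1, 26 at the lower share, 120 with no filter and 214 with tumour reads subtracted. The tumour share was 5.12% rather than 9.77% with untreated HepG2, 3.35% rather than 5.54% with 5 uM iMDK, 1.95% rather than 3.02% with 10 uM and 0.151% rather than 0.182% with Huh6 at 5 uM when all tumour-specific genes were the markers.

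Leaving out 1 library gave 3578 to 3900 genes for Huh6 at 0.3 uM PKF118-310, 7959 to 8112 at 0.4 uM, 4703 to 4850 at 5 uM iMDK, 7268 to 7389 at 10 uM, 7653 to 7843 between the PKF118-310 doses and 3175 to 3328 between the iMDK doses, and 215 to 242 at 0.2 uM. In HepG2 it gave 9968 to 10065 with PKF118-310, 6663 to 6969 with 5 uM iMDK, 7869 to 7969 with 10 uM and 1568 to 1875 between the doses, and 8407 to 8551 and 6108 to 6299 for the differences between lines. For macrophages with untreated HepG2 it gave 2467 to 3339. With untreated Huh6 it gave 92 to 246, with 92 without untreated co-culture replicate 1 and 102 without monoculture replicate 1. With HepG2 given 5 uM iMDK it gave 0 without untreated replicate 2 or iMDK replicate 3, 1 without iMDK replicate 2, 7 without untreated replicate 3 and 46 without iMDK replicate 1. At 10 uM it gave 206 without untreated replicate 2, 240 without iMDK replicate 2, 279 without iMDK replicate 3 and up to 636. With Huh6 given 5 uM iMDK it gave 0 without untreated replicate 2 or iMDK replicate 2, 1 without untreated replicate 1 or iMDK replicates 1 or 3 and 25 without untreated replicate 3. At 10 uM it gave 0 without iMDK replicates 1 or 3, 2 without untreated replicate 1 or iMDK replicate 2 and 62 without untreated replicate 3. Between the untreated co-cultures it gave 1569 without HepG2 replicate 2, 1610 without Huh6 replicate 2, 1601 without Huh6 replicate 3 and up to 2859. The difference between co-cultures gave 0 to 15, the latter without HepG2 iMDK replicate 1.

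Of 2034 alternative values of 174 called genes named in the tumour lines, 2016 kept their call and 18 lost it. In THP-1, 748 of 842 values of 56 called pairs kept it, 93 lost it and 1 changed sign. With the replicate block, 0 of the 82 named pairs in THP-1, called or not, lost a call and 6 gained one. Leaving out 1 library, without the block, ended a call in 55 of 498 values. Of 26 pairs not called in THP-1, 30 of 407 values passed and 43 changed sign. Over the whole pool that the naming rule gives, including genes left out of the text, 10711 of 11000 values of 1003 called pairs kept their call in the tumour lines and 2048 of 2436 values of 166 called pairs in THP-1, with 25 changing sign there. Gene lists kept 535 of 591 values in the tumour lines and 212 of 252 in THP-1, and most of the lost list calls came from the estimated correlation, so a list that passes only with the preset one is weakly founded.

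Of the genes named in the text that changed sign, only APOB had been called: its log2 fold change with untreated HepG2 was 0 after tumour reads were subtracted, by construction of that setting. LEF1 in HepG2 with PKF118-310 was -1.04 without PKF118-310 replicate 3 and 1.32 without vehicle replicate 2. With untreated HepG2, HLA-DRA was -0.38 without untreated replicate 3 and 0.96 without untreated replicate 2. With untreated Huh6, CD163 was -0.07 without monoculture replicate 2, -0.04 without monoculture replicate 3 -0.14 without untreated replicate 1 and 0.16 without monoculture replicate 1. CD274 was 0.21 without monoculture replicate 2 and -0.75 without untreated replicate 1. With HepG2 given 10 uM iMDK, CD163 was -0.06 with tumour reads subtracted, -0.01 at the lower share and without all libraries numbered 1, -0.06 without untreated replicate 2, -0.05 without untreated replicate 3 -0.25 without iMDK replicate 1 and 0.32 without untreated replicate 1. IL1B was -0.35 without iMDK replicate 1 and 0.72 without untreated replicate 1. TNF was -0.11 without untreated replicate 3, -0.25 without iMDK replicate 1 and 0.64 without untreated replicate 1. CD86 was -0.01 with DESeq2, no filter or RLE scaling, -0.02 with only the groups compared, -0.13 with tumour reads subtracted, -0.07 at the lower share, and -0.22 without all libraries numbered 1. It was -0.05, -0.03 and -0.15 without untreated replicates 1 and 2 and iMDK replicate 1, and 0.09 without iMDK replicate 2. LRP1 was -0.02 with DESeq2, no filter, RLE scaling or only the groups compared, 0 with the block alone or with only genes no higher, -0.1 with tumour reads subtracted, -0.06 at the lower share, and -0.18 without all libraries numbered 1. It was -0.05, -0.08, -0.11 and -0.06 without untreated replicates 1 and 2 and iMDK replicates 1 and 3, and 0.12 without untreated replicate 3. With Huh6 given 10 uM iMDK, IL1B was -0.43 and TNF -0.15 without iMDK replicate 1, and 0.82 and 1.02 without untreated replicate 1. CD86 there was 0 with tumour reads subtracted or without untreated replicate 2, -0.02 without all libraries numbered 1 and -0.03 without iMDK replicate 1. The p53 list reversed after subtraction with untreated HepG2 (adjusted p = 0.284) and with HepG2 given 10 uM iMDK (0.405).

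In the tumour lines the replicate numbers showed no shared structure. The mean correlation was highest with libraries of the same number for 3 of 18 Huh6 and 4 of 12 HepG2 libraries. The block moved no count of genes there by over 1.5 times. With Huh6 given 10 uM iMDK, where the numbers do not pair the libraries by the check used, CD163 passed with the block (adjusted p = 0.00163). In the tumour lines the block ended the calls of the ribosomal list in Huh6 at 0.3 uM PKF118-310 (0.0596), of aryl hydrocarbon receptor targets (0.0849) and hypoxia genes (0.115) in the differences between lines for PKF118-310 and iMDK, and of NALF2 (0.0517). The block changed no other call beyond those given with the comparisons. Without all libraries numbered 1, the calls of MT1E (0.0653) and MT2A (0.172) with untreated Huh6 ended, and MT2A also ended after subtraction (-0.95, 0.13, but 0.0356 at the lower share), with a size close to its main -0.96. With Huh6 given 10 uM iMDK, only the groups compared ended MARCO, APOB and APOA1 (0.304 each) and EPCAM (0.403), as did leaving out all libraries numbered 1 (0.195 to 0.792). MARCO also ended with only genes no higher (0.137) and at the lower share (0.0921).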

Other observations

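The list tests in this part were planned, and only setting the inhibitors and doses side by side was chosen after the results were seen. PKF118-310 and iMDK act on different targets, yet at 0.4 uM and 10 uM in Huh6 and 0.2 uM and 10 uM in HepG2 both raised TXNRD1, ATF3 and GDF15 and lowered AFP, GPC3 and MDK. Cholesterol synthesis genes fell with PKF118-310 and rose with iMDK in HepG2, and fell with both in Huh6 at these doses. Endoplasmic reticulum chaperones moved in the same directions, although their rise in HepG2 with 10 uM iMDK (adjusted p = 0.00279, then 0.126 with an estimated correlation) and their fall in Huh6 with PKF118-310 (0.0289, then 0.183) passed only with the preset correlation. Whether the responses to the inhibitors differ within a line was not tested.

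The only HepG2 library at 0.3 uM PKF118-310 gave medians of 2.69 for metallothioneins, 2.54 for aryl hydrocarbon receptor targets and 0.98 for NRF2 targets, against 2.04, 1.54 and 0.45 at 0.2 uM. Its medians for cholesterol synthesis (-1.43), hepatocyte genes (-1.28) and chemokines and cytokines (0.92) were smaller in size than the -1.73, -1.84 and 1.08 at 0.2 uM. Its Wnt/beta-catenin targets had a median of -0.39, at percentile 1.3 of 10000 random lists. With a single library these values have no error and the doses were not compared by a test.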
